A study of Caenorhabditis elegans with 2 samples.

How the data were processed

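The series measured binding of GFP-FLAG-tagged VAB-15 by ChIP-seq in whole starved L1 larvae of mixed sex, in 2 biological replicates of 1 group. Per the labels, chromatin was fragmented by sonication and recovered with an anti-GFP antibody, and a possible control experiment is named; it was not used here. The authors' files are peak lists. Each replicate and the pooled data have a deposited list of 30000 regions, described as peaks and background for the irreproducible discovery rate (IDR) procedure, and an optimal IDR-thresholded set was made from both replicates. Lists came on genome builds ce10 and ce11. Per the labels' notes beside the deposited files, the lists derive from alignments with a control alignment. The aligner, the peak caller and the thresholds are not given in the sources used here.

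Each deposited region carries the authors' signal value, a -log10 q-value and a summit offset. The signal of the authors was used only to describe, rank or filter regions within a list. The deposited -log10 q-value was used only to describe the lists: in the pooled ce11 list 2161 of 30000 regions had q at or under 0.01. The number of regions per list was preset, so the lists hold background by construction. Depth per sample is unknown, so no value could be scaled by it. The optimal sets held 990 peaks on ce11 and 1010 on ce10; 20 pairs of neighbouring ce11 peaks overlapped and were kept separate. The ce10 lists served only for counts and replicate agreement, and no coordinates were converted.

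Genes came from Ensembl release 115 (WBcel235, the same assembly as ce11), and sequence from the matching reference genome. Each summit took the first class that applied: promoter (1 to 1000 bp upstream of a protein-coding TSS), 5' UTR, coding exon, 3' UTR, intron, noncoding gene or intergenic. A summit within 2000 bp of its nearest protein-coding TSS was assigned to that gene. The TSS is the annotated 5' end of a protein-coding transcript. It was not measured here and may differ from where transcription starts. The background was the 15000 regions of lowest signal in the pooled ce11 list, called weaker regions, of which 62 overlapped an optimal peak and were left out, giving 14938. Shares were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within the 7 classes, the 7 chromosome tests and the 2080 6-mers. Gene lists were tested with an exact stratified hypergeometric test over 10 strata of territory length, the bases within 2000 bp for which a gene's TSS is the nearest, and adjusted over the 31 lists. Permutation tests used 100000 resamples. P-values treat peaks or genes as the units, which are not biological replicates.

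Motif windows spanned 101 bp around the summit. For each peak 5 unused windows from weaker regions of equal GC count were drawn, or the nearest count where none was left. When promoter peaks were taken separately, this matching failed. Only 3284 weaker promoter windows were there for 3165 draws, and the drawn windows averaged 39.9% GC against 46.97% in the peaks. That first comparison (odds ratio 1.50) was therefore replaced by a Mantel-Haenszel odds ratio stratified by GC count, applied to all peaks, promoter peaks and other peaks alike. The replacement was chosen after the first value had been seen. For 6-mers in promoter peaks alone, 1 matched window per peak was drawn. Since 41.9% of the weaker regions outside promoters lie in coding exons, and 5.32% of the peaks there, TAATTG and the 6-mers were also compared with coding exons left out of both sets, likewise after the data had been seen.

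The genes named are vab-15, the nearest genes within 2000 bp of the 20 strongest peaks, all bound members of the lists for touch receptor neuron genes, their fate regulators and Hox genes with cofactors, the 4 members with the strongest peaks of each other list with an adjusted p under 0.05, and the 5 6-mers with the smallest p. This rule, the tests and most alternatives were fixed before the data were examined. The alternatives changed the peak set, the replicate it had to appear in, distances, windows and backgrounds.

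The procedures were tested on simulated data. Among 200 simulated lists of 100 genes drawn without an effect 4.5% were called, and 77.5% of lists with a 3-fold effect, over 19967 genes. Simulated lists were called at p under 0.05 without adjustment, whereas the gene lists in the results were called after adjustment. Many of those lists are also smaller, such as the 10 Hox genes and cofactors. The 77.5% therefore does not give the power of the adjusted tests on such small lists. For lists of genes with long territories and no effect, the stratified test called 2.5% and Fisher's exact test 24%. A 6-mer inserted into 200 simulated windows ranked first of 2080. Those windows and their background were random bases of the same composition, without GC matching or coding sequence. The simulation therefore does not show how the 6-mer test behaves where peaks and background differ in sequence make-up. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.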

Results

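VAB-15 is a homeodomain protein of the Msx class that acts in the development of the touch receptor neurons of Caenorhabditis elegans. Its binding to the genome was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L1 larvae, the first larval stage, which had been starved after bleaching. The worms, of strain XIL99, carried a GFP-FLAG tag at the C-terminal end of VAB-15, inserted at vab-15 with CRISPR, and chromatin was recovered with an antibody against GFP. The series held 1 group of 2 biological replicates, so no treatment or genotype was compared. The questions the data can answer are where VAB-15 signal lay, near which genes, over which sequences, and how far both replicates shared it. The sequencing depth is unknown, since the peak lists carry no read counts, and the intervals given cover counting error over peaks only.

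The authors' optimal set held 990 peaks on ce11. Their strongest peak, at chromosome II 8328995 to 8329288, had a signal of 1191, which was 2.18 times that of the next. It lay 267 bp upstream of hel-1, which encodes an RNA helicase, inside the neighbouring gene C26D10.3. Across the set the signal, the authors' own value per peak, ran from 108 to 1191 with a median of 143. Of the 990 peaks, 177 lay on chromosome I, 168 on II, 181 on III, 146 on IV, 141 on V and 177 on X. These were exactly the 990 strongest of the 30000 regions in the pooled list.

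Both replicates held the strongest peaks. All 20 of the strongest ranked no lower than 22 in replicate 1 and 29 in replicate 2, and the hel-1 peak was first in each. Among all 990 optimal peaks, 838 (84.6%) had their summit in one of the 990 strongest regions of replicate 1, 655 (66.2%) in one of those of replicate 2, and 541 in both (54.6%, exact Clopper-Pearson 95% interval 51.5 to 57.8). Circular shifts of the peaks, 100 in number, gave 0.168% in both on average and at most 0.505%. The peaks were selected on the pooled signal of these same replicates, which largely fixes a share above that of shifted positions. The shifts therefore do not measure agreement of the replicates. If membership in the replicates' strongest regions had been independent within the optimal set, 56.0% would have been in both. With the 495 strongest regions of each replicate, 30.5% were in both (exact 95% interval 27.6 to 33.5), against 22.4% if independent. Selection on the pooled signal bears on these comparisons too, since a peak weak in 1 replicate needed more signal in the other to enter the set. Only 38 peaks lay in the 990 strongest regions of neither replicate. Independence within the set is therefore no measure of chance agreement, and neither comparison decides how far the replicates agree. Signal in the optimal set tracked replicate 1 (Spearman rho 0.877 across 987 peaks) more closely than replicate 2 (0.704 across 973 peaks), and rho between the replicates was 0.405 across 970 peaks. These are correlations across peaks, which are not independent replicates, and the peaks were selected on the pooled signal. Replicate 1 had the larger signal scale, with a median of 30.2 over its 30000 regions against 17.2 in replicate 2. The pooled signal may therefore weigh replicate 1 more. Whether this explains its closer tracking and larger share was not tested.

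**Figure D1:**
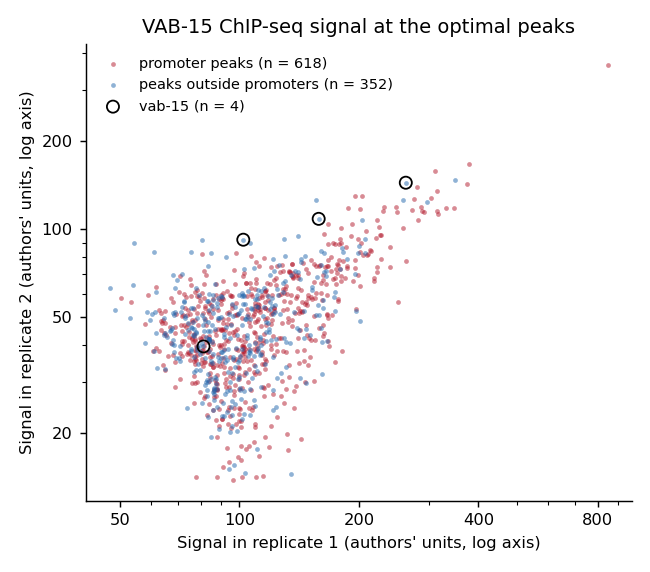
Signal of each optimal peak in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, for the 970 peaks found in both lists; red points are promoter peaks, blue points other peaks, and circles the 4 peaks at vab-15. The hel-1 peak stands alone at the upper right, and the weaker peaks spread widely (Spearman rho 0.405).

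VAB-15 peaks were concentrated in promoters and scarce in coding exons. Of the 990 summits, 633 (63.9%, exact 95% interval 60.9 to 66.9) lay 1 to 1000 bp upstream of a protein-coding transcription start site (TSS), against 21.98% of 14938 regions of lower rank in the pooled list, called weaker regions here (odds ratio 6.29, 95% interval 5.48 to 7.22; Fisher's exact test, adjusted p = 7.5e-162). Coding exons held 19 summits (1.92%) against 32.7% of the weaker regions (odds ratio 0.0402, exact test, adjusted p = 9.7e-131). By the same exact test introns held fewer (13.0% against 23.7%, odds ratio 0.483, adjusted p = 1.0e-15), and 3' UTRs held 5 (0.505% against 2.08%, adjusted p = 2.3e-04; 0.305% of the peaks in replicate 2's strongest regions). The shares in 5' UTRs (10 peaks, adjusted p = 0.321), noncoding genes (24 peaks, adjusted p = 0.917) and intergenic sequence (170 peaks, 17.2% against 15.5%, adjusted p = 0.225) did not pass the exact test. Against genome bases in place of weaker regions, the intergenic share was lower than the 21.6% of bases in that class (odds ratio 0.752, exact binomial test, adjusted p = 8.1e-04). With promoters of 500 bp, the intergenic share was 23.7% and higher than in the weaker regions (Fisher's exact test, adjusted p = 5.6e-04). Summits 500 to 1000 bp upstream of a TSS then no longer count as promoter and pass to later classes.

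**Figure D2:**
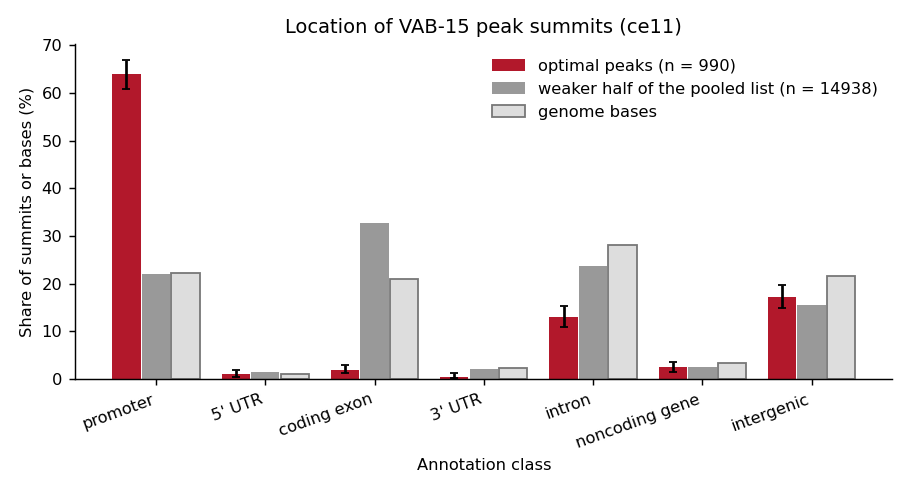
Share of summits or bases (y axis, percent) in each annotation class (x axis) for the 990 optimal peaks (red, with exact 95% intervals), 14938 weaker regions of the pooled list (dark grey) and all genome bases (light grey). Promoters hold 63.9% of the peaks and 21.98% of the weaker regions, and coding exons 1.92% and 32.7%.

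Along the chromosomes, peaks were more frequent in the middle of the autosomes (the central of 3 equal parts of each), which held 339 of 813 autosomal peaks (41.7%, exact 95% interval 38.3 to 45.2) against 32.1% of the weaker regions (odds ratio 1.52, Fisher's exact test, adjusted p = 1.8e-07). Chromosome V held fewer peaks than its share of weaker regions (14.2% against 18.5%, odds ratio 0.731, exact test, adjusted p = 0.0020). This call was lost by the exact test for peaks among the strongest regions of replicate 1 (15.2%, adjusted p = 0.0524), of both replicates (14.97%, adjusted p = 0.128), and for peaks at or above the median signal (14.9%, adjusted p = 0.157). No other chromosome passed the exact test, chromosome X included (17.9% against 15.5%, adjusted p = 0.110). Against genome bases, chromosomes I (odds ratio 1.23, exact binomial test, adjusted p = 0.0251), III (1.40, adjusted p = 1.6e-04), IV (0.819, adjusted p = 0.0369) and V (0.630, adjusted p = 6.8e-07) passed.

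Promoter peaks were somewhat more frequent among strong peaks. Of the strongest 247 peaks, 184 (74.5%) lay in promoters, against 150 (60.7%) of the weakest 247 (odds ratio 1.89, 95% interval 1.26 to 2.83; Fisher's exact test, p = 0.0015). Signal and distance to the nearest TSS were weakly related across the 990 peaks (Spearman rho -0.0763, permutation p = 0.0168). Ranked by the signal of replicate 2 alone, neither passed the test (odds ratio 1.41, p = 0.0867; rho -0.0183, permutation p = 0.568).

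The tagged gene itself held 4 peaks within 2000 bp of its TSS, more than any other gene by that count. vab-15 (WBGene00006881) lies on the plus strand of chromosome X from 9847275 to 9849805. Its strongest peak, at 9845981 to 9846256, had its summit 1154 bp upstream of the TSS in intergenic sequence; it ranked 16 of 990 with a signal of 403, and ranked 20 in replicate 1 and 5 in replicate 2. A weaker peak at 9846682 to 9847057 lay 405 bp upstream of the TSS, in the promoter, with a signal of 118.6. The other 2 peaks overlapped in the last intron, at 9848289 to 9848544 (signal 262) and 9848439 to 9848814 (signal 194). All 4 were among the 990 strongest regions of each replicate. Counting peaks within 2000 bp of the nearest TSS, only T26A8.4, eel-1 and sma-9, named after their values were seen, had 3 peaks each. Overlapping peaks were counted separately, so the lead of vab-15 may rest on the overlapping pair in its intron.

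**Figure D3:**
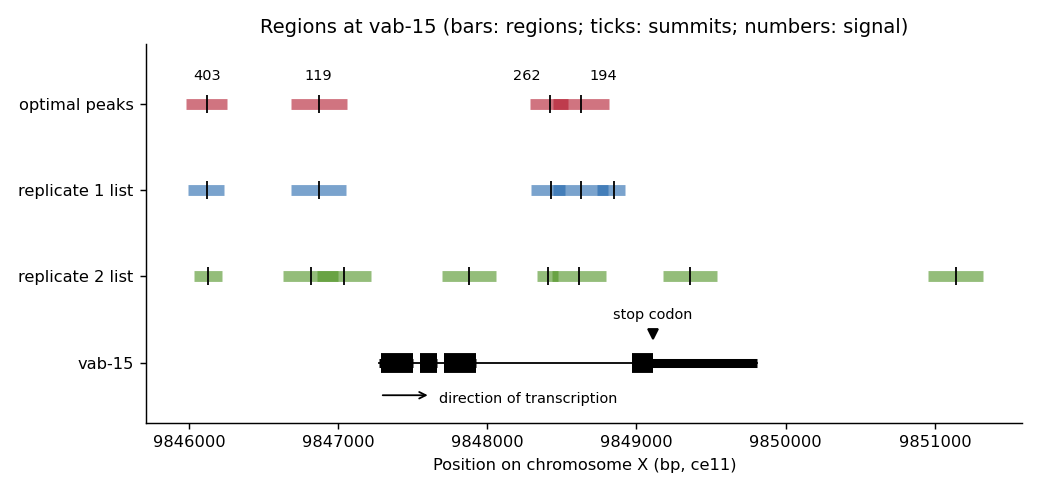
Regions at vab-15 on chromosome X (x axis, bp, ce11) in the optimal set and in the list of each replicate, with summits as ticks, the signal of each optimal peak above it, and the gene model below (thick boxes, coding exons; thinner boxes, UTRs). The 4 optimal peaks, with signals of 403, 118.6, 262 and 194, lie upstream of the gene and in its last intron.

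Most peaks lay close to the TSS of a gene. Within 2000 bp of a protein-coding TSS lay 810 of the 990 peaks (81.8%, against 67.9% of weaker regions), which assigned at least 1 peak to 774 genes, called bound here; 31 of these had 2 or more. The median distance from summit to TSS was 331 bp, against 1195 bp in the weaker regions. Among the 20 strongest peaks, 18 had a TSS within 2000 bp and 16 lay in promoters. After hel-1 came tasp-1 (signal 546, 61 bp upstream of the TSS), tub-2 (518, 38 bp upstream), cdc-48.1, which encodes an AAA ATPase of protein quality control (476, 170 bp upstream), ekl-4 (465, 151 bp upstream), C06B3.7 (448, 73 bp upstream) and iff-2, which encodes a translation initiation factor (431, 68 bp upstream). K12H4.5, W02G9.3, hsr-9, mppb-1, a subunit of the mitochondrial processing peptidase, puf-9, a Pumilio-family RNA-binding protein, and F17C11.4 had signals of 397 to 427. The peak of unc-49, which encodes GABA receptor subunits, lay in an intron 1270 bp upstream of the nearest TSS (signal 390). The 2 strong peaks without a TSS within 2000 bp, named after their values were seen, lay in introns of kcc-2, a potassium chloride cotransporter gene (signal 502), and fkh-7, a forkhead gene (signal 430).

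Of 31 gene lists fixed before the data were examined, 2 passed the exact stratified test. This test matches genes on territory length only, not on expression or promoter activity, which were not measured here. Neither call therefore shows that VAB-15 itself selects or avoids these genes. Ribosomal protein genes were bound more often than genes of like territory length, 22 of 76 against 3.14 expected (7.01 times, exact test, adjusted p = 4.0e-12). Counting every gene within 2000 bp of a summit, 45 of 76 were bound against 7.48 expected (6.01 times, exact test, adjusted p = 1.3e-25). The list was a name pattern, rpl or rps with a number, with or without a decimal suffix. It leaves out genes of the family with other names, such as rpl-7A (signal 202, 59 bp upstream of the TSS), named after its value was seen. The strongest peaks of listed genes were those of rpl-15 (signal 443, 348 bp upstream of the TSS), rpl-3 (423, 290 bp upstream), rpl-35 (401, 453 bp upstream) and rps-28 (373, 421 bp upstream). Chemoreceptor genes, a large family of G protein-coupled receptors mostly used in sensory neurons, were bound less often, 5 of 1353 against 45.3 expected (0.110 times, exact test, adjusted p = 2.4e-13). The 5 bound members of the list were srh-2 (signal 182), sre-23 (167), sri-5 (136), srpa-72 (122) and srd-43 (113), of which srd-43 falls outside the naming rule. This list, too, was a name pattern, str or sr with further letters, then a number. It can therefore hold genes that are not receptors, and srpa-72 is not to be read as a chemoreceptor gene. Among peaks in the strongest regions of replicate 2, that is without replicate 1, 2 chemoreceptor genes were bound (0.0659 times, exact test, adjusted p = 4.7e-10).

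Apart from the chemoreceptor genes, no list of neuronal or touch receptor genes passed the test. Of 14 touch receptor neuron genes, such as the mec channel and tubulin genes, 0 were bound, where 0.591 were expected, so fewer could not have been detected. Of 15 regulators of touch receptor neuron fate, 2 were bound, vab-15 itself and lin-14, a heterochronic gene (signal 126, 1943 bp downstream of a TSS), against 0.717 expected (2.79 times, exact test, adjusted p = 1). The lin-14 peak ranked 1279 in replicate 1 and 405 in replicate 2, and without replicate 2 the list was at 1.71 times its expectation. Of 10 Hox genes and cofactors, 2 were bound against 0.458 expected (exact test, adjusted p = 0.646): the Hox gene mab-5 (signal 134, 824 bp upstream of the TSS) and the Meis-class cofactor gene unc-62 (signal 169, 1045 bp downstream). Homeobox genes as a list had 5 bound of 100 against 4.20 expected, pan-neuronal genes 0 of 27 against 1.41, and neurotransmitter identity genes 0 of 21 against 0.680. In the pan-neuronal and neurotransmitter lists too, fewer could not have been detected. With expectations this low a modest excess could not pass either: the Hox list did not at 4.36 times. The lack of a call in these small lists is therefore no evidence that neuronal genes are unbound. Heterochronic genes, which time larval development, had 4 bound of 11 against 0.765 expected (exact test, adjusted p = 0.102), and heat shock genes 4 of 21 against 0.942 (adjusted p = 0.197). Counting every gene within 2000 bp of a summit, both of these lists passed (exact test, adjusted p = 0.0261 and 0.0042), and without strata of territory length heterochronic genes did (Fisher's exact test, adjusted p = 0.0061). The heterochronic ratio, 5.23 over all peaks, was 1.66 without replicate 2 and 0 among peaks in the strongest regions of both. Its 4 bound genes, named after their values were seen, were lin-28, lin-14 and lin-66, which ranked 1139, 1279 and 2211 in replicate 1, and daf-12, which ranked 575 there and had no region in the replicate 2 list. The ratio of heat shock genes was 1.89, against 4.24, among peaks in the strongest regions of both replicates.

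**Figure D4:**
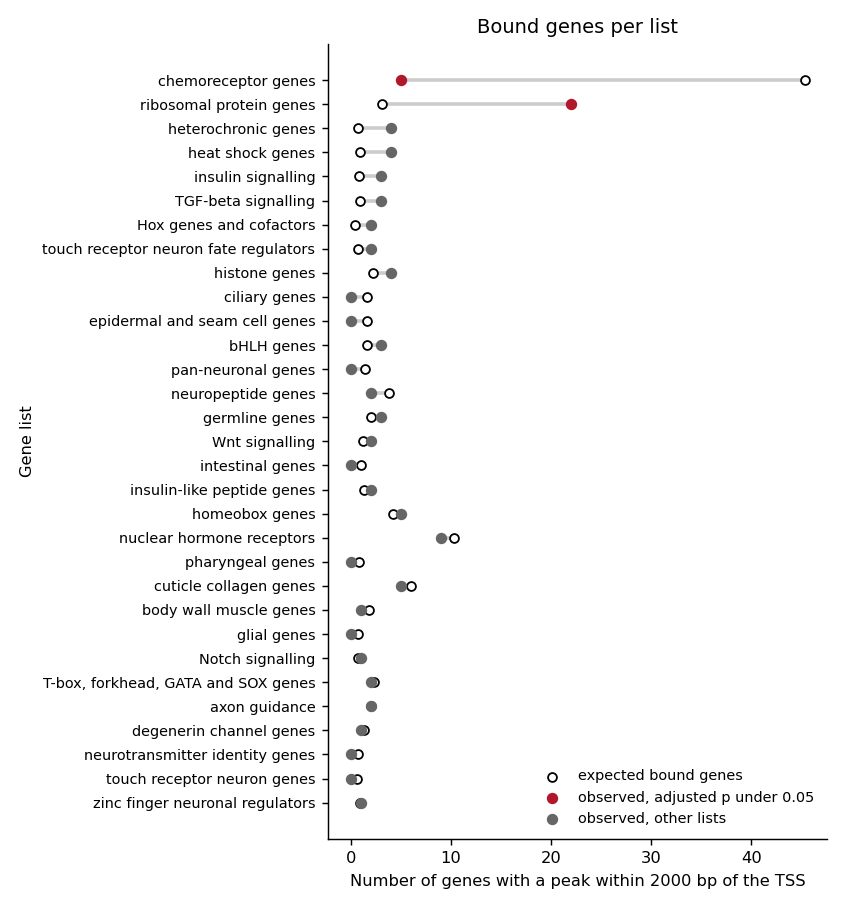
Number of genes with a peak within 2000 bp of the TSS (x axis) for each of the 31 lists (y axis), with observed (filled) and expected numbers (open), the latter from genes of like territory length; red marks an adjusted p under 0.05. Ribosomal protein genes (22 against 3.14) and chemoreceptor genes (5 against 45.3) stand apart from their expectation.

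The homeodomain core TAATTG, on either strand, was more frequent at peak summits than in weaker regions of like base composition, though most peaks lacked it. It lay within 50 bp of the summit in 103 of 990 peaks (10.4%, exact 95% interval 8.57 to 12.5) and in 4.38% of 4950 windows drawn from the weaker regions to match each peak's GC content, 5 per peak (odds ratio 2.53, 95% interval 1.96 to 3.25; Fisher's exact test, p = 2.4e-12). The match was close but not complete: GC content averaged 46.3% in peaks and 45.9% in the drawn windows, and 6.20% of draws had no partner of equal GC. Against windows centred 400 bp away in the same peaks, whose GC content was 35.7%, the odds ratio was 1.38 (95% interval 1.05 to 1.80, exact test, p = 0.0185). Without GC matching it was 1.57.

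**Figure D5:**
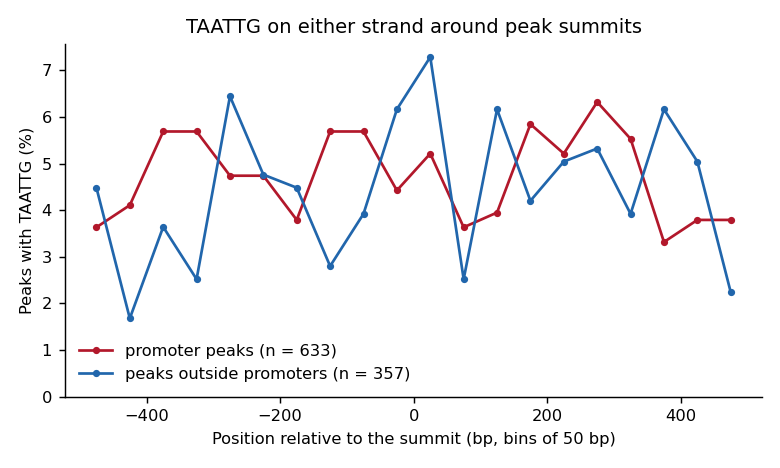
Share of peaks with TAATTG on either strand (y axis, percent) in bins of 50 bp around the summit (x axis, bp) for 633 promoter peaks (red) and 357 other peaks (blue). The bins on either side of the summit hold 6.16% and 7.28% of the other peaks, where bins farther away reach 6.44%, and 4.42% and 5.21% of the promoter peaks, where bins farther away reach 6.32%.

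Several GC-rich 6-mers were also more frequent at summits than in the matched windows. The 5 with the smallest p were GAGCGC (15.8% of peaks against 2.85% of matched windows, odds ratio 6.38, exact test, adjusted p = 3.4e-45), AGCGCG (12.4% against 2.48%, odds ratio 5.57), ACGCGC (12.7% against 2.63%, odds ratio 5.41), ACGCAG (13.6% against 3.82%, odds ratio 3.98) and GCGCAC (10.5% against 2.32%, odds ratio 4.94). Each was counted with its reverse complement. Of 2080 6-mers, 325 were more frequent and 370 less frequent in peaks after Benjamini-Hochberg adjustment of Fisher's exact test, and TAATTG stood in place 54 by p. Of the weaker regions 32.7% lie in coding exons, and of the peaks 1.92%, so the comparison also contrasts coding with noncoding sequence. With coding exons left out of both sets and 2 matched windows per peak, a comparison chosen after the data were seen, the odds ratios of these 5 ran from 2.73 (GCGCAC) to 3.66 (GAGCGC), and each passed the exact test. The odds ratio of TAATTG in that comparison was 2.33 (95% interval 1.72 to 3.16), and whether it differs from theirs was not tested.

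Peaks were close to tRNA genes more often than weaker regions. Of 990 summits, 32 (3.23%, exact 95% interval 2.22 to 4.53) lay within 500 bp of 1 of 612 annotated tRNA genes, against 0.723% of the weaker regions (odds ratio 4.59, 95% interval 2.97 to 6.90; Fisher's exact test, p = 8.9e-11). The odds ratio was 2.26 for peaks at or above the median signal (exact test, p = 0.0331), 7.64 within 200 bp and 2.92 within 1000 bp. The test was planned because genes read by RNA polymerase III are often seen in ChIP from whole worms. No ChIP of another protein was compared, so whether this nearness is particular to VAB-15 was not tested.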

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

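The GC-stratified and 2-window comparisons, those of promoter peaks and other peaks taken separately, flanks included, and those without coding exons were chosen after the data were seen; the other alternatives were planned. The promoter and autosome-middle shares, the core motif over all peaks and the tRNA share kept their direction and their side of the threshold under each alternative run, but the tRNA odds ratio ranged from 2.26 (peaks at or above the median signal) to 7.64 (within 200 bp). Keeping only peaks at or above the median signal left 495 peaks and 413 bound genes, and 228 6-mers less frequent in peaks. Requiring peaks to be in the strongest regions of both replicates left 437 bound genes and 225 such 6-mers. These sets are smaller by construction. Agreement of both replicates was 78.9% with 2 times as many regions per replicate and 30.5% with 495 regions. Counting every gene within 2000 bp, 4 lists passed; by nearest gene and without replicate 2 the heterochronic list, 1 of the 4, was at 1.66 times its expectation. Without coding exons and with 2 matched windows per peak, 214 6-mers were less frequent, against 305 with as many windows per peak and coding exons kept. With flanks of the same peaks as background, 546 6-mers were more frequent. TAATTG in promoter peaks did not pass against flanks (odds ratio 1.17); the flanks have lower GC content. By replicate 2 signal, the relation to distance was -0.0183 and the promoter odds ratio of strong peaks 1.41; the cause was not tested. The intergenic share turned from above the weaker regions to below genome bases (odds ratio 0.752); weaker regions hold less intergenic sequence than the genome. With promoters of 500 bp it passed upward (23.7%). Summits 500 to 1000 bp upstream of a TSS then leave the promoter class, whose share fell from 63.9% to 52.5%, so the intergenic call depends on the class boundary. The chromosome V call was lost in 3 of its alternatives, and chromosomes I, III and IV passed only against genome bases. For the core, the odds ratio was 2.33 with 2 matched windows per peak, 2.52 stratified by GC count and 2.39 so stratified without coding exons. Depth is unknown and could not be weighed.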

Other observations

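The tests on 7 further housekeeping lists, on TAATTG and 6-mers in promoter peaks and in other peaks taken separately, with their flanks and without coding exons, and on the repair template were chosen only after the data had been seen. Translation factor genes were bound in 9 of 40 cases against 1.52 expected (5.93 times, exact stratified test, adjusted p = 2.0e-04 over these 7 lists), with iff-2 (signal 431), eif-3.B (245) and eef-2 (233) the strongest. Proteasome genes had 5 of 33 against 1.26 expected and respiratory chain genes 6 of 45 against 1.69 (exact test, adjusted p = 0.0358 for each), the latter led by cox-5A (319) and cox-5B (292). Splicing factor genes (5 of 43, exact test, adjusted p = 0.118), mitochondrial ribosomal protein genes (5 of 70, 0.354), aminoacyl-tRNA synthetase genes (3 of 32, 0.354) and vacuolar ATPase genes (1 of 20, adjusted p = 1) did not pass. These tests, too, matched genes on territory length only.

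Among the 357 peaks outside promoters AGAGAG was the first 6-mer (23.8% against 6.55% of matched windows, odds ratio 4.46, Fisher's exact test, adjusted p = 2.0e-16), while GAGCGC led in the 633 promoter peaks (21.3% against 5.53%, odds ratio 4.63, adjusted p = 1.0e-13). AGAGAG was also found in 14.4% of the promoter peaks, and GAGCGC in 5.88% of the other peaks. Whether these shares differ between both kinds of peak was not tested, and the number of background windows per peak was 5 outside promoters and 1 in promoters. Coding exons hold 41.9% of the weaker regions outside promoters and 5.32% of the peaks there, so the AGAGAG comparison also contrasts coding with noncoding sequence. TAATTG was not shown to differ in share between promoter and other peaks (odds ratio 1.37, 95% interval 0.881 to 2.11, Fisher's exact test, p = 0.159). Of the 990 strongest regions of replicate 2, 338 lay outside the optimal set, and 49.1% of these were in promoters; for replicate 1 they were 155, with 49.7% in promoters.

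The first pattern weighed is that most peaks lie in promoters. GC content alone would have made the excess vanish against GC-matched regions, and it stayed (odds ratio 6.71, 95% interval 5.78 to 7.79), which argues against GC content as the whole cause. Coding exons were not left out here, and they hold 32.7% of the weaker regions and 1.92% of the peaks. The size of this odds ratio therefore also reflects the contrast of coding with noncoding sequence. Promoter signal without the homeodomain core was weighed next. Of the 633 promoter peaks, 59 (9.32%, exact 95% interval 7.17 to 11.9) held TAATTG within 50 bp of the summit, so most lay without this sequence. What the excess of the core in promoter peaks means stays open. At equal GC count, TAATTG was more frequent in promoter peaks than in weaker promoter regions (odds ratio 2.57, 95% interval 1.83 to 3.61), yet it was not detectably more frequent at their summits than 400 bp away (odds ratio 1.17, 95% interval 0.823 to 1.66), and those flanks are poorer in GC (36.3% against 46.97%). Both comparisons were given this role after an earlier, poorly matched value had been seen; the interval of the first lies above 1.5 and that of the second does not exclude 1, so neither is taken to decide.

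The second pattern is the core in peaks outside promoters, 44 of 357 (12.32%). GC content as the whole cause is argued against by GC-matched regions outside promoters, where the core stood in 5.55% of windows (odds ratio 2.39, 95% interval 1.60 to 3.52). Stratified by GC count, as for promoter peaks, the odds ratio was 2.67 (95% interval 1.91 to 3.73). Coding sequence in the background is argued against as the whole cause by the comparison without coding exons, stratified by GC count (odds ratio 2.50, 95% interval 1.76 to 3.56, 338 peaks against 6767 weaker regions); other differences in sequence make-up were not tested. Against windows 400 bp away in the same peaks the odds ratio was 1.79 (95% interval 1.14 to 2.79, Fisher's exact test, p = 0.0088), although those flanks are poorer in GC (34.6% against 45.2%); the interval excludes 1 but not 1.5, the bound written down before this value was computed, so an excess at the summit was seen and its size stays open. No biological explanation was tested.

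The third pattern is the 4 peaks at vab-15. Extra copies of the repair template used for tagging could raise signal near the stop codon. The strongest summit lies 2992 bp from it and the others 693, 486 and 2243 bp, so 1 of the 4 is within 500 bp, and the length of the template is not given in the sources used here; the explanation stays open for the intron peaks in particular. No biological explanation was tested.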
